A study of Danio rerio with 18 samples.

How the data were processed

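RNA from zebrafish trunk at 28 hpf was measured in 18 samples, 9 groups of 2, per the labels. They were MeRIP-seq inputs and m6A IPs of control and mettl3 morphant embryos, miCLIP of control embryos, RIP-seq of embryos injected with ythdf2-Flag mRNA, and RNA-seq of endothelial cells of control, mettl3 morphant and ythdf2 morphant embryos. MeRIP-seq started from isolated mRNA with an antibody of Synaptic Systems and miCLIP used one of Abcam, per the labels' protocols. Reads were paired, 151 bp in replicate 1 of the MeRIP libraries and 101 bp elsewhere, per the labels' protocols. How endothelial cells were isolated is not given in the sources used here.

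The authors deposited raw counts per gene in 16 tables of 33737 Ensembl gene IDs, made with TopHat2 2.0.9 and HTSeq (0.5.3p9 where a version is given), per the submitters' processing notes. The deposited m6A peak lists hold a fold enrichment per peak, 1 list per replicate, called with MACS2 per the submitters' processing notes. The deposited Ythdf2 RIP lists hold positions of regions alone, called with MACS2 per the submitters' processing notes, and the deposited miCLIP lists hold the position and strand of single sites, mapped with BWA 0.7.10 per the submitters' processing notes. Contig names in the peak and region lists are those of Zv9. The miCLIP lists name no build and no list states whether positions count from 0 or 1. Annotation release, strand setting of the counting, peak thresholds and the control used for RIP calling are not given in the sources used here. The first morphant peak list ended in 4842 lines without a fold that repeated control list 1 line by line, and these were left out. Reads outside annotated genes made up 9.07% to 13.5% of assigned and unassigned reads in MeRIP, 9.49% to 10.5% in endothelial and 42.9% to 43.8% in RIP libraries, and reads on more than 1 gene 2.00489% to 7.50%.

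Symbols came from a gene name table that covered 21939 IDs (65%) and are printed as that table gives them. All count columns mapped to a sample. Gene lists were fixed by hand before the data were examined: 18 lists with 684 members, of which 451 matched a single ID when case was ignored, 1 of them, dld, to another gene (DLD). So were the groups, the tests, most alternatives and the rule for named genes.

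Embryo and RIP counts were fitted with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr, Benjamini-Hochberg adjusted p, threshold 0.05) in R 4.3.3. Input libraries of the labels were compared in 1 fit of 4 libraries. IP over input, and its change between labels as an interaction, came from 1 fit of 8 MeRIP libraries. RIP was set against control inputs in a fit of 4 libraries. Gene lists in the inputs were tested with camera (preset correlation) and fry of limma 3.58.1, adjusted over the 18 lists, and their members also adjusted over the list alone. Replicate numbers were not used as a block. The self-test drew counts for the real genes with 200 genes changed. At 2-fold and 4-fold, 64% and 99% were recovered for the input comparison (22561 genes), 20% and 91% for the change of enrichment (23163 genes), and 4% and 34% for RIP (21005 genes), with 4.68%, 4.31% and 11.6% false calls.

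The columns of each endothelial group were planned as replicates. A chi-square of the columns of a group, over genes with at least 20 counts in them, gave 1.04, 1.01 and 1.04 per degree of freedom (p = 0.00162, 0.173 and 0.00402), and 1.02, 1.01 and 1.02 in genes under 1000 counts (p = 0.110, 0.179 and 0.0931). The small excess in the control and ythdf2 morphant columns lay in genes over 1000 counts (1.49 and 1.43 per degree of freedom). No other pair of the same groups exists to compare with, while the embryo and RIP pairs gave 59.4 to 338. The columns were therefore summed and taken as 1 sample per group, a departure from the planned test chosen after seeing the data. Genes with at least 20 counts in at least 1 pool were kept (13933). Folds are ratios of TMM-scaled counts with 95% exact intervals from the binomial distribution, which cover counting error only. Where a pool had 0 counts the fold is a bound against a floor of 3 counts over the pool, and such genes entered list medians at their bound. RIP folds of named genes with 0 to 3 counts over a group were computed in the same way. The 95% limit of a fold at the floor is smaller in size, such as log2 −8.58 for CASQ1 in the pool labelled mettl3 morphant, against −8.88 at the floor. In simulated pools the intervals held 97.5% of 200 known folds (13933 genes). A list's median was set beside 10000 random lists of the same size drawn from 10 expression bins, with the central range from percentile 2.5 to 97.5. Genes were drawn independently, so these ranges ignore that list members may vary together. Marked genes (log2 IP over input above 1 in control, adjusted p below 0.05) and RIP targets (log2 over control input above 1, adjusted p below 0.05) were treated the same way, with 1000 bootstrap resamples for intervals and a second matching on 5 bins each of endothelial and input level. The correlation of folds over the shared control was set beside 100 simulated draws of unchanged groups.

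Peaks, sites and regions were compared with bedtools 2.31.1 at an overlap of 1 bp, and miCLIP sites at the same position and strand, with exact binomial intervals. Background came from moving regions by 2000 and 10000 bp. Moved regions can leave the transcribed sequence, so this background does not account for shared expression. Peaks were not assigned to genes, since no Zv9 annotation was used here. The planned RIP gene sets were replaced by regions and by RIP counts per gene for the same reason.

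Depth sets the precision. With the RIP libraries, 3 counts are 0.380 and 0.569 CPM, in the endothelial pools 0.355, 0.351 and 0.410 CPM on their TMM-scaled library sizes, which all CPM of the pools use, and in the MeRIP libraries 0.0383 to 0.0915 CPM.

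Genes named in the text were fixed by rule. The first part named mettl3, ythdf2, notch1a, rhoca, runx1, myb, gata2b, kdrl, cdh5, efnb2a and dll4 in every comparison. The second took up to 10 genes with the largest rise and 10 with the largest fall among those past the threshold, with a mean of at least 5 CPM in the higher group, a symbol that is not a clone name, and no overlap between libraries. The third took up to 4 members of each list by adjusted p, which in the endothelial pools, where no p exists, became the 4 with the highest summed CPM. In the endothelial pools, without a p, the second part ranked by fold alone. For peaks the 5 strongest of those shared by both control lists stood in for genes, since the planned choice needed an annotation. Results of a few genes that this rule names are not reported here. The symbol RPS26 is carried by a pair of IDs and U1 by several.

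Alternatives were DESeq2 1.42.0, RLE size factors, total-count scaling, no low-count filter, the replicate number as a block, each library left out (the lone library of a group is then assumed to vary like the other groups), stricter overlaps, the better-ranked 50% of peaks, equal numbers of peaks, other definitions of marks and targets, and edgeR and DESeq2 on the 6 endothelial columns. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for tables and figures. Gene-level peak assignment, sequence motifs and position along transcripts were left out because they need the genome or annotation of the build.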

Results

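The data described the RNA methylation mark N6-methyladenosine (m6A) in the trunk of zebrafish embryos at 28 hours post-fertilization (hpf), and RNA levels after injection of morpholinos against mettl3 or ythdf2. Mettl3 is the enzyme that writes m6A on messenger RNA, and Ythdf2 is a reader protein that binds the mark and promotes decay of the bound transcript. The 18 samples formed 9 groups of 2. MeRIP-seq, which sequences RNA fragments pulled down by an m6A antibody (IP) beside the unselected RNA (input), covered control and mettl3 morphant embryos. miCLIP, which crosslinks an m6A antibody to RNA and reads the mark at single nucleotides, covered control embryos. RIP-seq recovered RNA bound to a Flag-tagged Ythdf2 made from injected mRNA. RNA-seq of endothelial cells, the cells that line blood vessels and from which blood stem cells emerge at this age, covered control, mettl3 morphant and ythdf2 morphant embryos.

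Counts on genes reached 32.8 M to 78.3 M in the MeRIP libraries. For replicates 1 and 2 they were 57.2 M and 68.0 M in control inputs, 38.0 M and 38.8 M in control IPs, 32.8 M and 50.01 M in morphant inputs, and 52.7 M and 78.3 M in morphant IPs. The RIP libraries held 7.90 M and 5.27 M, and the endothelial columns 4.75 M and 4.67 M (control), 3.94 M and 3.95 M (mettl3 morphant) and 3.57 M and 3.59 M (ythdf2 morphant). Genes with at least 1 count numbered 26417 to 27631 in MeRIP, 21426 to 21646 in RIP and 13079 to 15990 in endothelial columns. An unnamed gene took 16.4% to 20.5% of the counts in the MeRIP libraries of replicate 1 and 4.51% to 10.5% in those of replicate 2. Nothing in the labels says that replicates came from separate clutches or animals, so p-values measure only the spread between these samples, which may be technical.

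METTL3, the targeted gene, pointed opposite ways in the replicates of the embryo libraries. Its level was 35.8 and 19.6 counts per 1e6 gene counts (CPM) in the inputs labelled control, replicates 1 and 2, and 15.7 and 48.2 CPM in those labelled mettl3 morphant. The IP libraries gave 43.5 and 22.3 CPM for control and 17.7 and 55.2 CPM for morphant. METTL3 was lower under the morphant label in replicate 1 (log2 fold −1.16 in inputs) and higher in replicate 2 (1.27). A morpholino can block translation or splicing, so the transcript need not decrease. The embryo libraries are therefore referred to by their labels throughout. YTHDF2 stood at 26.6 and 37.2 CPM in control inputs and 26.5 and 36.5 CPM in morphant inputs.

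Some genes, picked after their values were seen, had the direction of METTL3. The cell cycle inhibitor gene cdkn1a had a log2 fold of −2.22 in the inputs of replicate 1 and 1.64 in those of replicate 2, labelled morphant over labelled control. The ubiquitin ligase gene mdm2 (−1.12 and 1.22) and the pro-apoptotic bbc3 (−1.58 and 2.14) did the same. The interferon-induced isg15 gave −2.40 and 3.002, and the heat shock genes hsp70l (1.46 and −2.16) and hsp70.3 (1.66 and −1.63) were opposed to these. The IP libraries, prepared from RNA of the same labels and numbers, repeated each of these directions and need not be a separate observation of them. In the DNA damage response list as a whole, 16 of 26 members had opposite signs in the inputs of the replicate numbers, with medians of −0.15 and 0.15. Opposite signs were also the more common case among all genes, of which 45.4% had the same sign in both, so this share alone does not set the list apart. Across 22561 genes the input folds of the replicate numbers had a Pearson correlation of −0.18 (Spearman −0.15). These are values across genes, which are not independent replicates. Over 21990 genes the IP folds gave −0.14 (Spearman −0.13).

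**Figure D1:**
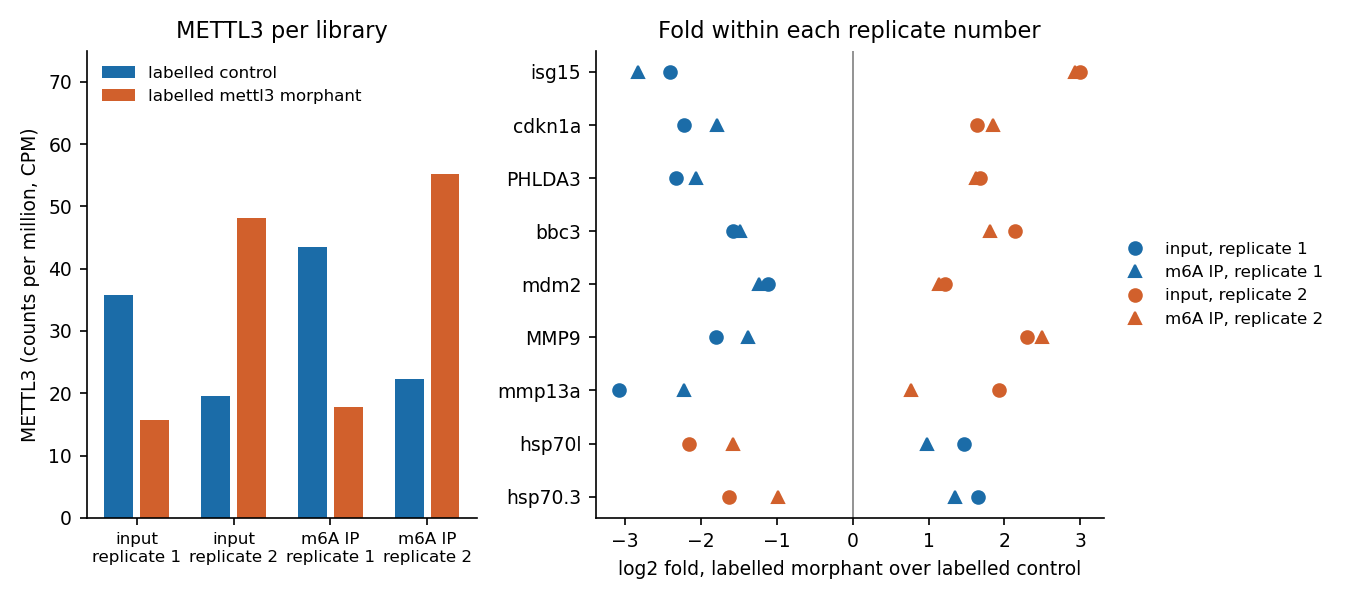
Left, METTL3 in CPM in each of the 8 MeRIP libraries, 1 bar per library, blue for those labelled control and orange for those labelled mettl3 morphant. Right, log2 fold of labelled morphant over labelled control for 9 genes within each replicate number, in inputs (circles) and m6A IPs (triangles), where all of replicate 1 (blue) lie on the other side of 0 from replicate 2 (orange).

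The input libraries asked which transcripts of the whole trunk differed between the libraries labelled mettl3 morphant and control. No gene passed an adjusted p of 0.05 among 22561 tested with edgeR, where 290 had an unadjusted p below 0.05, and DESeq2 called 1 gene. None of the vascular and blood genes fixed in advance was called. The Notch ligand dll4 had a log2 fold of −0.17 (SE 0.14), the blood stem cell factor MYB 0.24 (SE 0.26), the small GTPase rhoca 0.08 (SE 0.11), the haemogenic factor gata2b −0.37 (SE 0.55) and YTHDF2 −0.02 (SE 0.14). METTL3 itself had 0.10 with an SE of 0.72, and the vascular cadherin cdh5 0.00 (SE 0.12), each with n = 2 per label and an edgeR adjusted p = 0.9999. The DESeq2 gene has no symbol (log2 −5.29, adjusted p = 4.71e-13) and was looked up after its value was seen.

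Among the 18 gene lists, 3 were called lower in the inputs labelled morphant by camera, which compares a list with the other genes. Notochord and cartilage genes had a median log2 fold of −0.19 (14 members), skeletal muscle genes −0.16 (24 members) and neural crest and pigment genes −0.16 (17 members), with adjusted p = 0.00128, 0.00203 and 0.000930. With an estimated correlation between genes the adjusted p = 0.929 for each, and fry gave an adjusted p = 0.955. No member was called, either over all genes or adjusted over the list alone. The other 15 lists had adjusted p of 0.201 or more, with medians of −0.09 (myeloid), −0.01 (DNA damage response, Notch pathway, haemogenic), 0.01 (neural), 0.02 (endothelial, cytoskeleton), 0.03 (arterial, epidermis), 0.05 (cell cycle), 0.06 (m6A machinery), 0.08 (ribosomal), 0.09 (venous, erythroid) and 0.16 (interferon). Ribosomal protein genes had opposite signs in the replicate numbers for 57 of 60 members, with medians of 0.48 in replicate 1 and −0.34 in replicate 2. Leaving out morphant input 1 or 2 called 4 or 9 genes, the 4 being myhc4, si:ch211-153b23.5 and a pair of unnamed genes, named after their values were seen. With read length, which separates the replicate numbers, as a term, edgeR called 2 genes, an unnamed gene (log2 −5.18, adjusted p = 0.00148) and zgc:158463 (4.92, adjusted p = 0.00148), also named after their values were seen.

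The IP libraries asked which genes carried m6A, read as a higher share of counts after pulldown than in input. In the libraries labelled control, 3209 of 23163 genes were higher in IP and 3424 lower (edgeR, adjusted p below 0.05, n = 2 per group), of which 1120 and 1438 differed at least 2-fold. The most enriched were the zinc finger gene znf977 (log2 2.102, SE 0.23, adjusted p = 0.00158), the mitochondrial MT-ND6 (2.098, SE 0.20, adjusted p = 0.00146) and the chromatin remodelling gene rsf1b.1 (2.09). Next came the splicing regulator NSRP1 (2.004, SE 0.26, adjusted p = 0.00212), followed by rab11fip1b (1.88), oc90 (1.83), col23a1b (1.80), rbmx2 (1.78) and VKORC1L1 (1.76). At the other end RPL30 had −2.69 (SE 0.31, adjusted p = 0.00164), the complex III subunit UQCRQ −2.40, RPS26 −2.39, the muscle parvalbumin pvalb2 −2.38, RPLP0 −2.37, pon2 −2.35, RPL37 −2.34, RPS21 −2.32, LSM2 −2.30 and RPL10 −2.28.

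Of the genes fixed in advance, YTHDF2 was enriched at log2 1.34 (SE 0.20, adjusted p = 0.00274) and dll4 at 0.91 (SE 0.15, adjusted p = 0.00384). The haemogenic MYB (0.48, adjusted p = 0.190) and rhoca (0.30, adjusted p = 0.115) did not pass, nor did cdh5 (−0.08), METTL3 (0.16) or gata2b (−0.05). No single gene ID carried the names notch1a, kdrl or efnb2a, so these have no value here. Values are relative to the median gene, since scaling centres them. Scaled by total counts alone, 1685 genes were higher and 977 lower, and leaving out 1 library gave 1113 (control input 1) to 2071 (control IP 1) higher genes.

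In the libraries labelled mettl3 morphant, 3085 genes were higher in IP and 3126 lower, 965 and 1351 of them at least 2-fold. NSRP1 (log2 1.91, SE 0.26, adjusted p = 0.00269), MT-ND6 (1.91), znf977 (1.64) and rsf1b.1 (1.60) were again among the most enriched, with gpatch4 (1.85), PPP1R37 (1.74), tmem151a (1.67), B3GNT3 (1.63) and SH3TC2 (1.61). The lowest were the integrin gene itgae.1 (−3.67, SE 0.64, adjusted p = 0.00638), LSM2 (−2.28), UQCRQ (−2.26), RPS26 (−2.26), pon2 (−2.18), RPS21 (−2.14), tspan34b (−2.13), pvalb2 (−2.12), get1 (−2.12) and RPL30 (−2.05). YTHDF2 had 1.47 (adjusted p = 0.00251) and dll4 0.95 (adjusted p = 0.00363), while rhoca (0.24), MYB (0.41), gata2b (0.29), cdh5 (−0.09) and METTL3 (0.14) were not called. Total-count scaling gave 1150 higher and 960 lower genes, and leaving out 1 library gave 1481 (morphant input 2) to 2749 (morphant IP 1) higher genes.

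Enrichment was shared between the labels. Of the genes higher in IP, 2616 were called in both, and 697 of the 1388 genes enriched at least 2-fold in either were so in both. Across genes the log2 enrichments had a Pearson correlation of 0.821. The test of the change itself called 0 of 23163 genes with edgeR, with 72 at an unadjusted p below 0.05, and 1 gene, unnamed, with DESeq2. The difference in enrichment was 0.12 for YTHDF2 (SE 0.28), 0.05 for dll4 (SE 0.21), −0.06 for rhoca (SE 0.18), −0.07 for MYB (SE 0.36), 0.34 for gata2b (SE 0.78), −0.01 for cdh5 (SE 0.33) and −0.02 for METTL3 (SE 1.11), none past the threshold. Genes enriched at least 2-fold in either condition had a median log2 IP over input of 1.05 and 1.23 in control replicates 1 and 2, and 0.95 and 1.24 in morphant replicates 1 and 2. The range of the morphant values held that of the controls. METTL3 pointed opposite ways in the replicates, so no direction of m6A loss was read from this test. Without morphant input 2, mt-atp8 was called (−4.42, edgeR adjusted p = 0.0443), named after its value was seen.

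**Figure D2:**
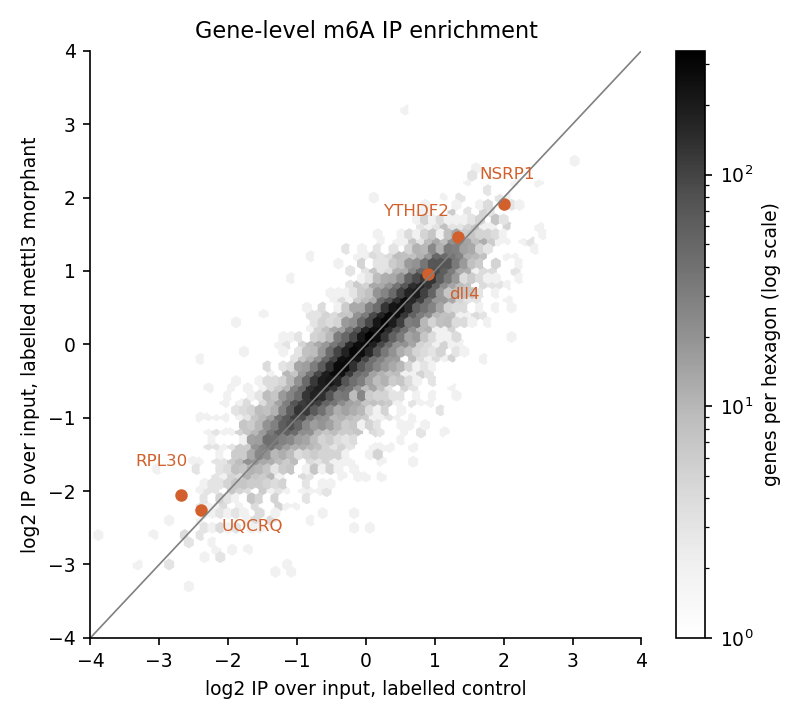
Log2 IP over input of each gene in libraries labelled control (x axis) and labelled mettl3 morphant (y axis), with darker hexagons holding more genes and the line of equal values in grey. NSRP1 (2.004 and 1.91) and YTHDF2 (1.34 and 1.47) lay at the enriched end and RPL30 (−2.69 and −2.05) and UQCRQ (−2.40 and −2.26) at the other.

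Deposited peak lists gave the methylated regions themselves, 1 list per replicate. The lists labelled control held 32131 and 23819 peaks and those labelled mettl3 morphant 27289 and 14878, with median lengths of 266 to 275 bp, covering 11053, 8243, 9187 and 4923 kb. The control lists shared 20625 peaks, 64.2% of list 1 (95% exact interval 63.7% to 64.7%) and 87.6% of list 2. Of the shared control peaks, 56.4% (55.8% to 57.1%) overlapped a peak in both morphant lists, 32.5% in 1 of them and 11.03% in neither. In the other direction 95.3% of the 12384 peaks shared by the morphant lists lay in both control lists and 0.61% in neither. With equal numbers of peaks per list these shares were 62.7% and 10.99%, and with the better-ranked 50% of each list 75.5% and 5.86%. By single lists, 70.9% of control list 1 lay in morphant list 1 and 42.4% in morphant list 2, against 64.2% in control list 2, and 74.6% of control list 2 lay in morphant list 1. A list with fewer peaks gives fewer overlaps. With the better-ranked 50% of each list the share in both morphants was 39.1%.

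The 5 strongest of the peaks shared by both control lists, by the authors' fold in control list 1, also overlapped a peak in both morphant lists. They lay on chromosome 8 at 17085171 to 17085570 (fold 173), chromosome 15 at 44268630 to 44269052 (159), chromosome 22 at 626553 to 626972 (150.4), chromosome 2 at 10494413 to 10494663 (124) and chromosome 8 at 4708207 to 4708592 (123). Coordinates are those of the deposited lists, whose contig names follow the Zv9 assembly, and no Zv9 annotation was used here, so the genes at these positions are not given. In the order given, the 5 peaks had folds of 25.7, 87.9, 67.4, 44.7 and 120.4 in control list 2. Morphant list 1 gave 20.2, 6.73, 8.34, 5.41 and 12.8, and morphant list 2 gave 6.93, 72.7, 59.8, 47.2 and 75.4. The peaks were picked by their fold in control list 1, which favours that list. The chromosome 15 peak held 6 miCLIP sites in each miCLIP list. The peak at 4708207 on chromosome 8 held 3 and 4 sites, that on chromosome 22 held 1 and 3, that on chromosome 2 held 1 and 0, and the strongest peak held 0 in both. Peaks of higher fold in control list 1 were found again in both morphant lists more often, at 50.1%, 57.3%, 57.3% and 61.1% for 4 groups of equal size from lowest to highest fold. Peaks with a miCLIP site present in both miCLIP lists, 24.8% of the shared control peaks, were found again in 81.2% (80.1% to 82.3%) of cases, against 48.3% (47.5% to 49.1%) without.

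**Figure D3:**
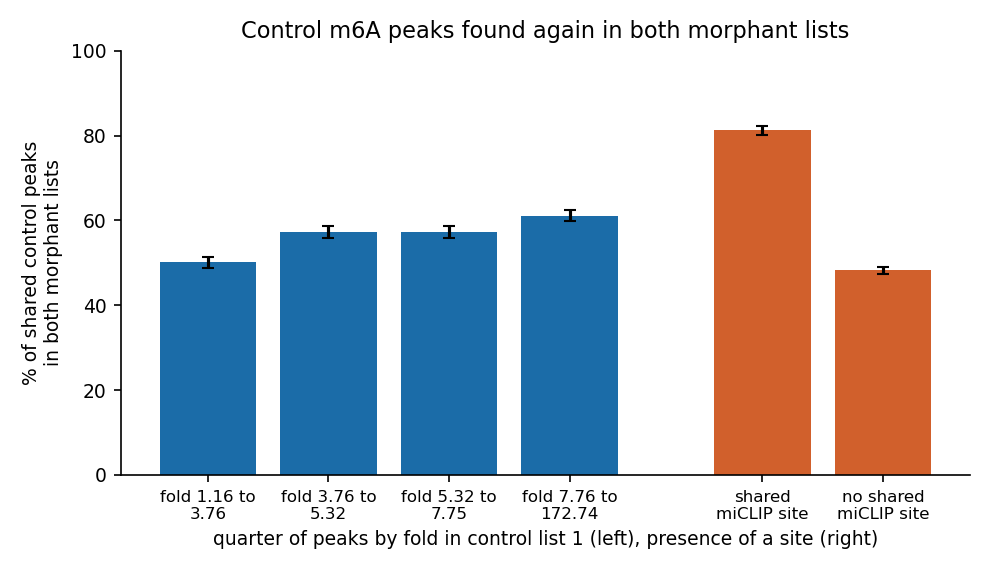
Percent of the 20625 peaks shared by both control lists that also overlapped a peak in both lists labelled mettl3 morphant, in 4 groups of equal size by the authors' fold in control list 1 (blue) and by presence of a shared miCLIP site (orange). Error bars are 95% exact binomial intervals, which cover counting error only. The bars run from 50.1% to 61.1% over the fold groups and stand at 81.2% and 48.3% with and without a site, not matched on transcript level.

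miCLIP placed m6A in control embryos at 49873 and 46365 single positions, of which 21695 had the same position and strand in both lists (43.5% and 46.8%). Of the 21474 shared sites on nuclear chromosomes, 54.6% (54.0% to 55.3%) lay inside a peak of both control MeRIP lists and 64.0% inside a peak of either. The same sites moved by 2000 or 10000 bp lay inside in 5.09% and 2.0995% of cases. Moved sites can leave the transcribed sequence, so this background does not separate shared m6A from shared expression. MeRIP and miCLIP used antibodies of different vendors, per the labels. The mitochondrial genome held 221 shared sites, 217 of them on the plus strand. Of the gaps between consecutive shared nuclear sites on the same strand, 38.6% were at most 100 nt.

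The Ythdf2 RIP lists held 55886 and 43371 regions, and 52.7% of list 1 and 67.8% of list 2 overlapped the other list, against 7.70% and 7.02% of list 1 after moving it by 2000 and 10000 bp. Of the 29455 shared regions, 32.4% (31.8% to 32.9%) overlapped a peak of both control m6A lists, 45.0% one of either list and 17.0% a shared miCLIP site, where moved regions gave 4.48% and 3.74% for the peaks. As with the miCLIP sites, the moved regions do not separate m6A from shared expression. Seen from the m6A side, 46.7% of shared control peaks carried a shared RIP region. That share was 53.8%, 47.4%, 44.4% and 41.4% from the lowest to the highest fold group. Which control library the regions were called against is not given in the sources used here.

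At gene level the RIP libraries asked which transcripts Ythdf2 bound, read as higher counts in RIP than in control inputs. Among the genes of highest fold, 5_8S_rRNA had a log2 fold of 13.03 (SE 1.77, edgeR adjusted p = 0.0144), which was not called over morphant inputs (6.67, adjusted p = 0.116) or without RIP library 1 (11.62, adjusted p = 0.0860). The spliceosomal RNA U2 had 10.74, the histone genes h2ax2 9.78, hist1h2a4 9.33 and hist1h2a11 9.33, and SNORA62 9.37. U1, 1 of several gene IDs of that name, had 49 RIP counts and 0 in the control inputs and was at least 599-fold higher. Ratios of summed counts gave snord118a 9.98 (interval 8.06 to 13.06), U12 9.78 (7.85 to 12.87) and SNORA23 9.10 (7.46 to 11.43), on 2, 2 and 3 input counts. Over morphant inputs the fitted folds were 5.79 for U1, 6.61 for U2, 5.79 for snord118a, 5.45 for U12, 6.13 for SNORA23 and 7.68 for SNORA62, with edgeR adjusted p of 0.0167 to 0.0431. The inputs were mRNA, per the labels, so RNAs without a poly(A) tail can differ between these library types whatever Ythdf2 binds. This was not tested. Inputs also differed among themselves, with 36774 counts of 5_8S_rRNA in morphant input 1 against 843 in the control inputs together. Lowest were the mitochondrial MT-ND3 (−5.87, SE 0.71, adjusted p = 0.00937), atp5md (−5.82), TOMM5 (−5.40), atox1 (−5.21), GLO1 (−5.03), NDUFB11 (−5.02), COX7A2 (−4.84) and RPL30 (−4.83). Ratios of summed counts gave LSM2 −5.84 (−11.14 to −3.36) and tmsb −5.13 (−8.17 to −3.27), on 1 and 2 RIP counts. YTHDF2, whose tagged mRNA had been injected, stood at 3.24 (SE 0.64, adjusted p = 0.0349). dll4 (1.77, adjusted p = 0.0656), rhoca (−1.85, adjusted p = 0.0739), MYB (−1.02), METTL3 (−1.19) and cdh5 (−0.48) were not called. In all 1325 genes were higher and 1190 lower of 21005, with n = 2 libraries per group. These folds are relative to the trimmed mean of genes and rest on that scaling. Scaled by total counts, which moved the median gene by −1.92 log2 to −2.11, 382 genes were higher and 14288 lower. YTHDF2 then had 1.33 and was not called (edgeR adjusted p = 0.0529), dll4 turned to −0.13 (adjusted p = 0.818), and rhoca (−3.79), MYB (−2.97), METTL3 (−3.09) and cdh5 (−2.43) were called lower. The total of 2515 fell to 360 or 286 without control input 1 or 2, which also ended the YTHDF2 call (adjusted p = 0.365 and 0.331). It stood at 11136 and 7082 without RIP library 1 or 2, and DESeq2 called 5270.

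Genes high in RIP were more often m6A-enriched. Of 20924 genes tested in both, 1255 were at least 2-fold higher in RIP and 1011 at least 2-fold enriched in control IP, and 195 were both, where independence gives 60.6. That is 15.5% of RIP genes against 4.15% of the others, an odds ratio of 4.25 (95% interval 3.59 to 5.03, two-sided Fisher's exact p = 1.35e-50). Matched on input level the odds ratio was 3.97 (Mantel-Haenszel), and across genes the RIP and IP folds had a Pearson correlation of 0.320. Both folds were taken over the same control inputs, which by itself raises this overlap. With RIP taken over the morphant inputs instead, the odds ratio was 3.62. These are mRNA inputs of the same library type, so the swap cannot remove what both folds share against any such input. With RIP scaled by total counts, which left 320 RIP genes, the odds ratio was 1.76 (1.17 to 2.64).

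The endothelial columns entered as 1 sample per group. The 2 columns of each group differed by little more than sampling noise, with a chi-square per degree of freedom of 1.04 (control, chi-square p = 0.00162), 1.01 (mettl3 morphant, p = 0.173) and 1.04 (ythdf2 morphant, p = 0.00402), where the other replicate pairs gave 59.4 to 338. The small excess in control and ythdf2 morphant columns lay in genes over 1000 counts (1.49 and 1.43). The columns of a group were counted as 1 sample and summed. The pools held 9.42 M, 7.89 M and 7.15 M counts. With 1 sample per group there is no replicate check and no p-value, intervals cover counting error only, and each comparison below compares those libraries, not the conditions. Within a group 3.33%, 3.06% and 3.46% of genes differed at least 2-fold between columns. Between pools 52.0% did for mettl3 morphant against control and 54.4% for ythdf2 morphant against control. Scaling by total counts moved the median gene by 0.27 and 0.19 log2, from −0.15 to 0.12 for mettl3 and from −0.18 to 0.01 for ythdf2, so folds are relative to the trimmed mean of genes. CPM of the pools use the same TMM-scaled library sizes, while CPM of the embryo libraries are per 1e6 gene counts without that scaling.

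The targeted genes were not lower in their own pools. METTL3 stood at 21.7 CPM in the control pool, 129 CPM in the pool labelled mettl3 morphant and 30.6 CPM in that labelled ythdf2 morphant, a log2 fold of 2.57 (95% interval 2.35 to 2.81) and 0.49 (0.20 to 0.78) over control. YTHDF2 stood at 8.27, 6.56 and 25.4 CPM, a log2 fold of −0.33 (−0.87 to 0.19) and 1.62 (1.21 to 2.04). Neither pool therefore showed a knockdown in transcript level, and the directions below rest on the labels.

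In the pool labelled mettl3 morphant, the blood stem cell factor MYB was 1207-fold lower than in control, at 3.05 against 3678 CPM (26 against 31122 counts, log2 −10.24, interval −10.85 to −9.69). In the embryo inputs, MYB lay between 9.19 and 16.1 CPM. RUNX1, the master regulator of blood stem cell emergence, had 0 counts in all 3 pools, which allows up to 0.355 CPM in control, but also only 1 to 10 counts in each embryo input. Among the other large falls, the striated muscle kinase gene spegb stood at −10.03 (interval −15.33 to −7.55), the calcium channel subunit genes CACNB1 at −9.44 and CACNA1S at −8.86 (−14.17 to −6.38), muscle glycogen phosphorylase PYGM at −9.22 (−14.53 to −6.74) and SMPX at −8.77, and the calcium store protein gene CASQ1, at 0 counts, was at least 471-fold lower. EYA1 (−9.65), gspt1 (−9.58) and the hatching enzyme gene he1.1 (−8.90, −11.18 to −7.35) completed the list. The vascular GTPase gene rhoca was higher by 1.03 (0.91 to 1.16), dll4 by 0.28 (0.18 to 0.38), and gata2b, with 0 control counts and 14 morphant counts, at least 4.63-fold. cdh5 had −0.20 (−0.48 to 0.07), and 0.06 scaled by total counts.

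Among the highest folds in this pool, MIR142, a microRNA gene of blood cells, was 461-fold higher (log2 8.85, interval 7.62 to 10.47, with 5, 2326 and 13 counts in control, mettl3 and ythdf2 pools), and the myeloid factor SPI1 stood at 239.8 against 2.48 CPM (6.59, 5.98 to 7.29). The lymphoid factor IRF4 had 6.80 (4.93 to 9.86), TBXAS1 6.57, the neuronal factor NEUROD6 7.80 (5.31 to 13.11), ANKRD27 7.06, the matrix gene MATN3 6.92, SERPINE3 6.91, KLHL32 6.84 and the sterol synthesis enzyme CYP51A1 6.65, most with 1 or 2 control counts. In all 2690 genes were at least 2-fold higher and 4321 lower of 13492 with a fold. Of the 13933 genes kept, 328 had over 100 counts in one pool and 0 in the other.

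In the pool labelled ythdf2 morphant, MYB was 257-fold lower than in control (14.3 CPM, log2 −8.00, interval −8.29 to −7.73), and cdh5, the cadherin of endothelial junctions, stood at 3.14 against 28.6 CPM (−3.19, −3.87 to −2.57). The neural homeobox gene GSX1 had −10.24 (−15.55 to −7.76). The flow-responsive factor klf2b and the neural factor pou3f1, both at 0 counts, were at least 218-fold and 212-fold lower. RC3H1 (−8.40), lmo7b (−8.20), tshz3a (−8.06), the claudin gene cldnb (−7.92, −10.97 to −6.06) and MTIF2 (−7.75) followed. gata2b, which acts upstream of runx1 in haemogenic endothelium, was at least 130.1-fold higher (338 counts against 0), rhoca was higher by 1.66 (1.54 to 1.78) and dll4 by 1.45 (1.36 to 1.53). Other high folds were FJX1 7.88 (5.39 to 13.19), BRD1 7.67, the patterning factor EN1 7.46 (4.96 to 12.77), BMP1 7.26, TESC 7.05, PFAS 7.04, GPR85 6.96 and ITPR3 6.84, and TTLL11 was at least 121-fold higher. In all 2955 genes were at least 2-fold higher and 4440 lower of 13596, and 292 had over 100 counts against 0.

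The 2 morphant pools differed from each other as much as from control, with 7105 genes at least 2-fold apart of 12923 (3620 higher and 3485 lower in the pool labelled ythdf2 morphant) and 435 with over 100 counts against 0. Higher in the ythdf2 pool were he1.1 (log2 10.40, 8.85 to 12.68), rlf (9.25), syne1b (9.05), cyp4t8 (8.82) and muscle genes, with TNNC1, a troponin subunit of slow and cardiac muscle, at 8.91 (7.55 to 10.79), CKMT2 8.78, CACNA1S 8.28 and spegb 8.07. tnnt2d and acte1 were at 0 in the mettl3 pool and at least 495-fold and 377.5-fold higher. Lower were SPI1 (−10.78, −16.08 to −8.30), GSX1 (−10.03), RC3H1 (−8.24), BRIP1 (−7.91), GRWD1 (−7.87), ms4a17a.8 (−7.62), MBTD1 (−7.56), ccdc170 (−7.51) and klf2b (at least 227-fold). Of the genes fixed in advance, METTL3 had −2.08, cdh5 −2.98, YTHDF2 1.95, MYB 2.23, gata2b 4.81, dll4 1.17 and rhoca 0.62. The log2 CPM of genes had a Pearson correlation of 0.747 between the morphant pools, against 0.765 and 0.751 of each with control.

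Genes of the vascular lineage were higher in both morphant pools as lists. Endothelial markers had a median log2 fold of 0.99 in the pool labelled mettl3 morphant and 1.58 in that labelled ythdf2 morphant, with 14 and 19 of 28 members at least 2-fold higher and 1 and 2 lower. Both medians stood above all of 10000 random lists of the same size and expression (percentile 100). Random genes were drawn independently, while list members can vary together (estimated correlation 0.19 for this list in the embryo inputs). The percentiles here and below therefore describe a position and are no test. The scavenger receptor gene stab2 went from 1065 CPM in control to 1911 and 2469 CPM, plvapb from 816 to 2135 and 1472 CPM, she from 369 to 696 and 1109 CPM, and ramp2 from 405 to 820.0 and 691 CPM. Arterial markers had 0.87 and 1.095 (percentiles 99.6 and 99.95), with 4 and 6 of 12 members higher, such as dlc (185, 331 and 516 CPM), flt1 (158, 294 and 394 CPM) and HEY2 (46.7, 165 and 361 CPM). Venous markers had 1.32 and 1.36 (percentiles 99.99 and 99.9), with 5 and 5 of 8 higher and 0 and 1 lower, such as tek (54.4, 261 and 170.4 CPM), stab1 (123, 194 and 352 CPM) and lyve1b (131, 359 and 135 CPM).

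The Notch pathway, which sets arterial and haemogenic fate, had medians of 0.50 and 0.61 (percentiles 97.8 and 99.1). This list holds DLD, a metabolic enzyme gene whose symbol matched the ligand dld when case was ignored, and without it the medians were 0.55 and 0.65 (percentiles 98.1 and 99.1). Its members split, with 8 higher and 2 lower of 26 in the mettl3 pool and 7 and 7 in the ythdf2 pool. The ligand gene dlc was higher, while the glycosyltransferase gene LFNG went from 330.3 to 222 and 139 CPM, and adam10a from 180.1 to 296 and 215 CPM. Haemogenic and blood stem cell genes had 0.60 and 1.01 (percentiles 98.0 and 99.9), with 8 higher and 3 lower of 19, and 9 and 5 of 18. MYB went against this list, LMO2 went with it (103, 301 and 307 CPM), and CEBPB had 604, 915 and 319.6 CPM and MYCN 95.3, 81.3 and 137 CPM. Cytoskeleton and adhesion genes of the endothelial-to-haematopoietic transition had 0.67 and 0.60 (percentiles 99.2 and 98.4), with 5 higher and 1 lower, and 4 and 4, of 18. rac1a had 379, 725 and 614 CPM, CDC42 294, 601 and 612 CPM, rhocb 159.7, 320.3 and 467 CPM, and the catenin gene CTNNB1 542, 426 and 599 CPM. The arterial list shared 5 matched members with the Notch list, and the endothelial list shared 4 with the venous and 4 with the haemogenic list.

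Markers of muscle and red blood cells were lower in both morphant pools. Skeletal muscle genes had a median of −3.85 in the mettl3 pool and −2.18 in the ythdf2 pool (both percentile 0), with 23 and 21 of 23 members at least 2-fold lower and 0 higher. The calcium pump gene atp2a1 went from 16951 CPM in control to 455 and 3722 CPM, tropomyosin tpma from 13875 to 738 and 2311 CPM, the myosin gene myhz1.1 from 6785 to 469.9 and 1364 CPM, and creatine kinase ckmb from 6393 to 419 and 1494 CPM. The list held 6.77% of control counts, 0.436% and 1.76% in the morphant pools, and 4.38% in the embryo inputs, where the endothelial list held 0.428%, 1.16%, 1.21% and 0.0486%. Erythroid genes had −3.79 and −3.78 (both percentile 0), with 14 of 16 and 15 of 15 lower. Embryonic globins hbae3 (102, 28.6 and 11.3 CPM) and hbbe3 (62.0, 16.8 and 4.50 CPM) and the haem enzyme UROD (45.7, 21.9 and 13.8 CPM) were among them. The member with most counts, TMOD4 (382, 22.3 and 92.6 CPM), is a tropomodulin of muscle fibres.

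**Figure D4:**
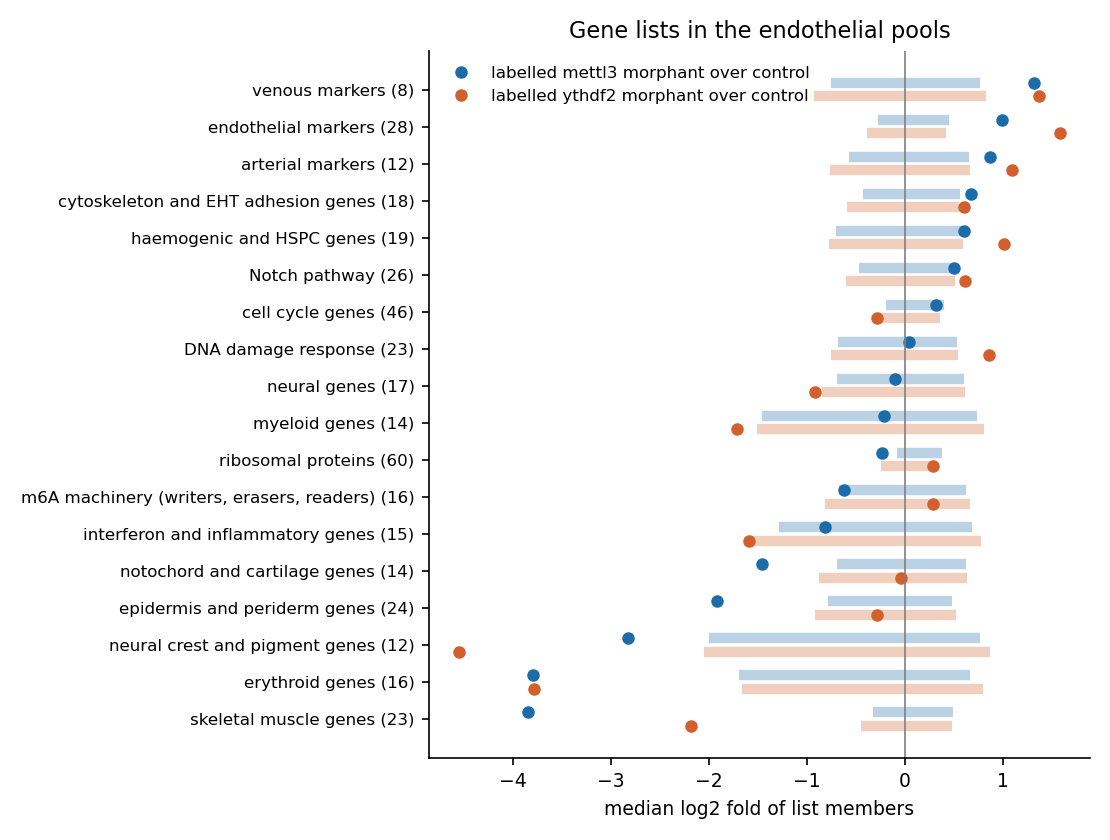
Median log2 fold over control of the members of each of the 18 gene lists (points) in the pool labelled mettl3 morphant (blue) and that labelled ythdf2 morphant (orange), with pale bars for the central 95% of 10000 random lists matched on expression; numbers in brackets are members measured for mettl3. Endothelial (0.99 and 1.58) and venous (1.32 and 1.36) lists lay above their bars and muscle (−3.85 and −2.18) and erythroid (−3.79 and −3.78) lists below, while with total-count scaling, which moved the median gene by 0.27, the neural, myeloid and ribosomal medians of the mettl3 pool turned positive.

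Epidermis and periderm genes had −1.91 in the mettl3 pool (percentile 0.02, 13 of 24 lower and 1 higher) and −0.29 in the ythdf2 pool (percentile 32.8), with the keratin krt4 at 461, 109 and 295 CPM, but krt18a.1 at 2583, 4241 and 6499 CPM, krt8 at 1795, 1919 and 4355 CPM, and pfn1 at 324, 580.4 and 623 CPM. Notochord and cartilage genes had −1.46 (percentile 0.1, 8 of 14 lower and 0 higher) and −0.04 (percentile 53.03), with the collagen genes col9a3 at 229, 78.3 and 311 CPM and COL9A2 at 306, 218 and 592 CPM, MATN4 at 579, 369 and 405 CPM, and the coatomer gene COPA at 181, 264 and 429.6 CPM. Neural crest and pigment genes had −2.83 and −4.54 (percentiles 0.51 and 0, 9 and 11 of 12 lower and 0 higher), with the melanosome genes pmela at 105, 0 and 18.4 CPM and DCT at 79.4, 7.03 and 0 CPM, twist1a at 94.4, 48.97 and 16.1 CPM, and TFAP2A at 42.2, 56.0 and 0 CPM. Neural genes had −0.11 (percentile 39.7, and 0.16 with total-count scaling) and −0.92 (percentile 1.87, 8 of 17 lower), such as tubb5 at 502, 436 and 266 CPM, SOX3 at 231, 214 and 95.8 CPM, sox19a at 199, 196 and 76.7 CPM, and GFAP at 106, 182 and 67.0 CPM. Myeloid genes had −0.21 (0.06 with total-count scaling, percentile 48.5) and −1.71 (percentile 1.38, 8 of 14 lower), yet ARPC1B (55.2, 100.3 and 147 CPM), srgn (34.5, 94.4 and 70.7 CPM) and LCP1 (19.6, 49.1 and 49.7 CPM) were higher in both pools.

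Of the stress, growth and RNA lists, DNA damage response genes had 0.04 in the mettl3 pool (percentile 62.6) and 0.86 in the ythdf2 pool (percentile 99.8, 7 higher and 4 lower of 23). CCNG1 stood at 772, 896 and 1487 CPM and sesn3 at 64.9, 146 and 122 CPM, while BTG2 went the other way at 2346, 1509.8 and 466 CPM. Interferon and inflammatory genes had −0.82 (percentile 9.98) and −1.59 (percentile 2.4, 9 of 17 lower), with nfkbiab at 294, 137 and 75.6 CPM, cxcl18b at 234, 79.3 and 9.15 CPM, irf1b at 38.2, 42.6 and 12.7 CPM and MYD88 at 37.1, 57.3 and 2.59 CPM. Cell cycle genes had 0.32 (percentile 92.0) and −0.28 (percentile 3.21), with PCNA at 1105, 1012.5 and 931 CPM, MCM5 at 285, 387 and 221 CPM, RRM1 at 285, 311 and 223 CPM, and mki67 at 303, 211 and 196 CPM. Ribosomal protein genes had −0.24 in the mettl3 pool (percentile 0.1; 0.03 with total-count scaling, which moves every gene, random lists included, by 0.27 and leaves the percentile as it is) and 0.28 in the ythdf2 pool (percentile 96.9). RPL3 (6373, 4191 and 4915 CPM) and RPS2 (5441, 4739.7 and 4977 CPM) had most counts with RPL4 (4992, 3399.9 and 4407 CPM) and RPLP0 (4182, 2863 and 4202 CPM). The m6A machinery had −0.62 (percentile 3.27) and 0.28 (percentile 82.8), with igf2bp1 at 440.3, 312 and 328 CPM, ZC3H13 at 117, 58.2 and 162 CPM, IGF2BP3 at 86.2, 129 and 81.5 CPM, and hnrnpc at 65.9, 79.6 and 87.1 CPM.

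Set directly against the mettl3 pool, the ythdf2 pool had higher muscle (median 1.87, percentile 100, 17 of 22 members at least 2-fold higher), epidermal (1.44, percentile 99.9, 15 of 21), notochord (1.72, percentile 99.99, 8 of 14) and ribosomal genes (0.54, percentile 100). Crest and pigment genes (−3.30, percentile 0, 6 of 8 lower), neural genes (−0.70, percentile 2.08) and cell cycle genes (−0.57, percentile 0.06) were lower. The endothelial (0.18, percentile 85.4), Notch (−0.06, percentile 39.3), arterial (0.28), venous (−0.59), haemogenic (0.40), cytoskeleton (0.07), erythroid (0.22), myeloid (−0.42), DNA damage response (0.31), interferon (0.98) and m6A machinery (0.08) lists lay within the central 95% of random lists.

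**Figure D5:**
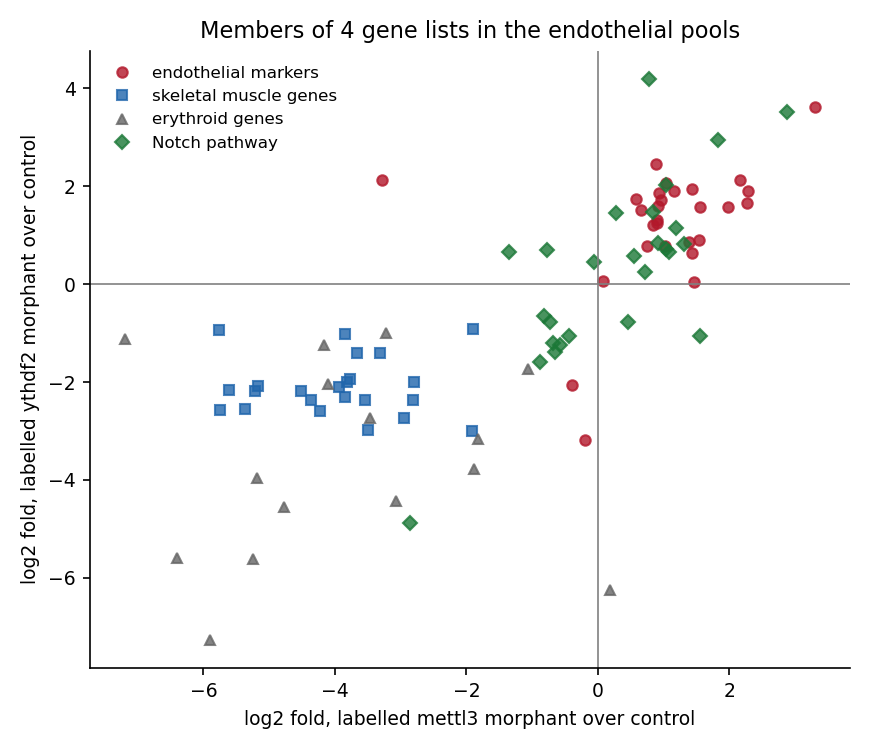
Log2 fold over control of single members of 4 gene lists in the pool labelled mettl3 morphant (x axis) and that labelled ythdf2 morphant (y axis), 1 point per gene. Muscle genes, with medians of −3.85 and −2.18, filled the lower left and most endothelial markers the upper right, while Notch members lay in all 4 quadrants.

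Both morphant folds used the same control pool, so they share its chance values. Across 13155 genes they had a Pearson correlation of 0.448 (interval 0.434 to 0.461), and 65.0% of genes had the same sign. Unchanged groups simulated against that control gave 0.481 and 66.0% with counting noise, and 0.492 and 66.4% with the spread of the embryo inputs. The observed covariance was 2.08, against 0.0512 and 0.156 in these simulations. Genes at least 2-fold higher in both numbered 1091, where independent lists give 449.7, and those lower in both 2477, where independent lists give 1458. The opposed directions held 457 (794 if independent) and 562 (826). MYB, CASQ1 and atp2a1 were lower in both pools and rhoca higher in both. The control is 1 sample and cannot be split, so part or all of the excess may come from it, and the observed correlation lay below the simulated ones.

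Whether m6A-bearing transcripts or Ythdf2 targets stood apart in the morphant pools was asked with sets from the embryo data. Genes enriched at least 2-fold in control IP, such as YTHDF2, had a median log2 fold 0.06 above other genes in the pool labelled mettl3 morphant (523 genes, interval −0.10 to 0.25) and 0.14 above in that labelled ythdf2 morphant (537 genes, −0.02 to 0.42). Among random sets matched on expression these stood at percentiles 96.2 and 99.3, and at 87.3 and 97.2 when matched on embryo input level as well. In the ythdf2 pool the value turned to −0.03 when every gene with significant enrichment counted as marked. Genes at least 2-fold higher in RIP had −0.03 (578 genes, −0.18 to 0.14, percentile 90.3) and −0.06 (598 genes, −0.28 to 0.10, percentile 75.6). With RIP scaled by total counts these were 0.28 and −0.09. None of the 4 intervals of the TMM-scaled sets excluded 0. METTL3 and YTHDF2 transcripts were not lower in their pools, so these values follow the labels alone.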

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

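All tests weighed here were chosen only after the results were seen.

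The haemogenic factor gata2b had folds of unlike sign in embryos and endothelial pools under the same label. Its log2 fold of labelled mettl3 morphant over control was −0.15 and −0.47 in the inputs of replicates 1 and 2, and 2.21 in the endothelial pools, a bound that rests on 14 counts against 0. The inputs held 14 and 25 counts in control and 7 and 13 in morphant libraries. Their fitted fold was −0.37 (SE 0.55), so a direction in embryos is not established. The difference was not tested. The mitochondrial genome, which no comparison of nuclear m6A sites used, held 221 miCLIP sites in both lists, of 241 and 253 per list, with 217 on the plus strand. Reads outside annotated genes reached 43.8% in RIP library 2 and 42.9% in RIP library 1, against 9.07% to 13.5% in the MeRIP libraries.

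METTL3 and some genes such as cdkn1a, picked after their values were seen, went opposite ways in the replicate numbers of the embryo libraries. With the number as a block, exchanging the labels within 1 number called 180 genes in the inputs, against 2 for the labelled split. In the IP libraries the exchanged split called 133 genes, against 3 for the labelled split. Under that block the exchange swaps the tested difference and the spread it is set against. These counts therefore restate the opposite folds and are no separate test of a cause. A batch or read length that acts alike on both libraries of a number cancels from folds within that number, whatever the splits call. Input depth was lower under the morphant label in both numbers, with ratios of 0.573 and 0.74, which does not turn between them. Labels exchanged within 1 number are a candidate explanation that stays open, as does a different morpholino response of separate clutches, which was not tested.

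Skeletal muscle genes such as atp2a1 were lower and endothelial markers such as plvapb higher in both morphant pools. Lower depth of the morphant pools is argued against by the endothelial share of counts, which was 2.71 times the control share for mettl3, where the depth ratio was 1.19. A higher endothelial share that lowers every other cell type alike is argued against in the mettl3 pool by the neural list. Its median of −0.11 lay within its random lists, while the muscle, erythroid, epidermis, notochord and crest medians lay below theirs. In the ythdf2 pool the neural list (−0.92) lay below its random lists, as did the muscle, erythroid, crest and myeloid lists. The notochord (−0.04) and epidermis (−0.29) lists lay within. The test had named the neural list of the mettl3 pool alone, so it decides nothing for the ythdf2 pool. Fewer muscle cells in the morphant samples may account for the muscle part, where 23 of 23 measured members were at least 2-fold lower in the mettl3 pool and 21 in the ythdf2 pool. These counts are the pattern itself, so they do not favour fewer cells over an effect of the morpholino. With 1 sample per group, a change in sample purity and an effect of the morpholino stay open.

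Fewer m6A peaks were listed under the mettl3 morphant label, 27289 and 14878 against 32131 and 23819. Depth of the IP libraries is argued against, since those labelled morphant had 1.39 and 2.02 times the counts of control. Depth of the inputs, lower at ratios of 0.573 and 0.74, and lower m6A in the morphants cannot be told apart. The median log2 IP over input of marked genes differed by −0.107 in replicate 1 and 0.017 in replicate 2, but scaling centres such values and METTL3 itself went opposite ways in the replicates.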

How the results depend on the processing

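Alternatives for the RIP counts, the pooled endothelial columns, region overlaps of RIP, the Notch list without DLD and definitions of marks and targets were chosen after seeing the data, and the others were planned. Of the main results under all alternatives, 140 values stayed within their limits, 47 moved and 1 turned, and of named genes and lists 1783 stayed, 146 moved, 47 turned, 23 lost a call and 14 gained one. The values that stayed include endothelial ones with a column of a pool left out. Columns of a pool differed by little more than sampling noise, so such values could hardly move. The cause was not tested for any of the changes, except where fewer libraries entered.

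Among counts of called genes, DESeq2 gave 1 for the inputs, 1 for the change of enrichment and 5270 for RIP, and total-count scaling gave 1685 and 1150 genes higher in IP in control and morphant and 14670 called in RIP, most of them lower. Without the low-count filter RIP gave 5482. RLE factors gave 3389 and 3184 genes higher in IP and 3103 in RIP, and RIP over morphant inputs gave 2082. Leaving out 1 library, with the lone library of a group assumed to vary like the other groups, gave 0 to 9 genes in the inputs, 1113 to 2071 and 1481 to 2749 genes higher in IP in control and morphant, 0 to 1 for the change, and 286 to 11136 for RIP. In the RIP fit dll4 (log2 0.96 to 2.30 leaving out a library, −0.134 with total counts), rhoca, cdh5, MYB and METTL3 gained a call under some alternatives. Calls of rab11fip1b, oc90, rbmx2, PPP1R37, B3GNT3, itgae.1, 5_8S_rRNA and, in RIP, YTHDF2 were lost under at least 1 alternative.

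With the replicate number as a block, 2 genes were called in the inputs, an unnamed gene and zgc:158463, named after their values were seen, with 4203 and 4080 genes higher in IP, 3091 in RIP, 0 for the change of enrichment and 3 lists. The block gave 0.382 for the correlation of endothelial folds. Libraries of the same number deviated together in MeRIP (correlation 0.138 to 0.448, number and read length being one) and not in endothelial columns (−0.0238 to 0.0122), and with only 2 numbers they are not taken as pairs.

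Reciprocal overlap of 50% gave 59.4% of control peaks shared, 51.1% of these in both morphant lists, 41.6% of RIP regions shared and 19.1% of them with a peak. The better-ranked 50% of peaks gave 51.98% shared and 39.1% in morphants, and equal list lengths 50.6%. Single lists gave 42.4% to 74.6% of control peaks in morphants, 49.6% to 50.6% of miCLIP sites in peaks and 24.1% to 26.7% of RIP regions with a peak. Peaks of either list gave 64.0% of miCLIP sites and 45.05% of RIP regions, a miCLIP site in place of a peak 16.99%, and miCLIP sites within 5 nt 44.8%.

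The count of genes at least 2-fold apart between endothelial pools stayed within 1.5 times, with 6469, 6871 and 6836 for edgeR and 6240, 6627 and 6657 for DESeq2 on the 6 columns, called and 2-fold, and 6858 to 6981, 7309 to 7403 and 6982 to 7020 leaving out a column. The rank correlation of endothelial folds was 0.417. Marked genes turned to −0.0277 in the ythdf2 pool with any enrichment, and ribosomal genes to 0.0295 in the mettl3 pool with total counts, which move every gene alike. Targets, whose percentiles lay within the central 95%, also changed sign within their intervals, which was not counted as turned, from −0.03 to 0.12 and 0.07 against expression-matched genes and to 0.0213 with RIP above both inputs in the mettl3 pool, and from −0.06 to 0.07 and 0.065 against matched genes in the ythdf2 pool. Estimated correlation left 0 embryo lists, and leaving out a library 3 to 5. The odds ratio of RIP and marked genes lay between 3.62 and 5.23 (3.28 and 5.01 matched on input level), and at 1.76 (1.67) with RIP scaled by total counts, which put targets in the mettl3 pool at 0.28.

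Genes that turned were uncalled throughout, except dll4 in RIP. Leaving out a library, the inputs gave MYB −0.0360 to 0.55, YTHDF2 −0.14 to 0.0947, METTL3 −0.72 to 0.76 and cdh5 −0.0666 to 0.0721 (−0.00413 without the filter). Control IP over input gave cdh5 −0.23 to 0.0939 (0.00784 with total counts), METTL3 −0.61 to 0.82 and gata2b −0.64 to 0.35 (0.0774 with total counts), and morphant IP over input gata2b −0.12 to 0.57, cdh5 −0.54 to 0.27 and METTL3 −0.74 to 0.96. The change of enrichment gave YTHDF2 −0.12 to 0.33, gata2b −0.0766 to 0.91, rhoca −0.16 to 0.0342, dll4 −0.0681 to 0.15 (−0.00482 with total counts), MYB −0.41 to 0.21, cdh5 −0.46 to 0.34 (0.0149 without the filter) and METTL3 −0.92 to 0.77 (0.0162 without the filter).

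TMM factors from genes without peaks and sets built from peaks per gene were not run, for lack of an annotation, nor the better-ranked 50% of RIP regions, which carry no score. Estimated correlation in the endothelial pools needs more than 1 sample per group. In simulated counts 4% of 2-fold changes were recovered for RIP, against 64% in the inputs.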

Other observations

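The genes and tests below were chosen after their values were seen.

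Several genes had wide opposite folds in the replicate numbers of the embryo inputs, labelled morphant over labelled control. The collagenase gene mmp13a had log2 folds of −3.08 and 1.93 in replicates 1 and 2, the gelatinase gene MMP9 −1.81 and 2.29, the interferon-related gene helz2a −2.32 and 1.76 and the chemokine gene cxcl18b −1.44 and 1.86. The apoptosis-related PHLDA3 (−2.33 and 1.68) and casp8, a protease of the death receptor pathway (−0.80 and 0.78), did the same. The chaperone gene HSPA2 went the other way at 1.59 and −1.76. Of the interferon and inflammatory list 16 of 22 members had opposite signs, with medians of −0.27 and 0.42. Most genes of the inputs also had opposite signs, with 45.4% of the same sign in both. Some members of the DNA damage response list lay near 0 in both, such as SESN1 (−0.01 and −0.17), EI24 (0.06 and 0.02) and gtse1 (−0.01 and −0.06). The globin gene hbae1.1 had 2.52 and −2.44 in inputs but −0.18 and −0.41 in IP libraries.

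Comparing replicate 1 with replicate 2 called 452 genes in the inputs and 1783 in the IP libraries (edgeR), far more than the labels did, a structure that goes with read length. Exchanging the labels of replicate 2 without a block called 0 genes in the inputs (869 at an unadjusted p below 0.05) and 1 in the IP libraries, si:dkey-204l11.1 (log2 −3.30, adjusted p = 0.0468). METTL3 was not used to move any library to another group.

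Myeloid genes held 0.0181% of counts in the control pool, 0.0602% in the pool labelled mettl3 morphant and 0.0374% in that labelled ythdf2 morphant, and in the mettl3 pool the myeloid factor SPI1 stood out at 239.8 CPM (TMM-scaled). Epidermal genes held 0.533%, 0.767% and 1.27% of counts in the 3 pools against 3.60% in the embryo inputs. The RIP libraries held YTHDF2 at 44.2 and 116.6 CPM, against 26.6 and 37.2 CPM in control inputs, all per 1e6 gene counts.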
